A study of Mus musculus with 17 samples.

How the data were processed

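Livers of male C57BL/6 mice given TCDD (tetrachlorodibenzo-p-dioxin, a persistent activator of the aryl hydrocarbon receptor, AhR) in sesame oil by oral gavage were profiled by Molecular Cartography, a probe-based imaging assay that records the position of single transcripts in tissue. Per the labels, gavage was repeated every 4 days for 7 administrations, tissue was taken on day 28 after the start, and the dose groups received 0 (sesame oil alone), 0.3, 3 or 30 µg/kg. Per the labels, frozen sections of 10 µm from 2 animals per dose were imaged by the assay's provider. The 17 sections came from 8 animals. Each animal had a section on slide 4 and on slide 5, and the slide 5 section of TCDD 30 replicate 1 was deposited as 2 regions. The labels mark the animals of a group as biological replicates and the slides as technical ones.

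Each deposited file lists detected transcripts, with the 3 pixel coordinates and the gene symbol of each, as the authors deposited them, without cell outlines. The spot-calling filters, the software version and the length of a pixel are not given in the sources used here, so distances are in coordinate units. Transcripts were summed here into counts per gene and section from the deposited positions. No further normalization of the deposited values was found. All 98 gene symbols of the panel matched a mouse gene name in the reference table. Genome coordinates are not used here because no build is stated. The panel was chosen before imaging, so shares among its genes say nothing about genes outside it.

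Sections were divided into squares of 250 coordinate units, and a bin with at least 20 transcripts was taken as tissue. Counts of all sections of an animal were summed, so the animal was the replicate (n = 2 per dose, 8 in all). The p-values rest on the spread between animals, estimated jointly over the 4 groups. Abundance was tested with limma voom (limma 3.58.1, R 4.3.3) on the animal sums, after median-of-ratios scaling, for genes with at least 10 transcripts in at least 2 animals. Abundance levels are given in CPM, counts divided by the scaled total of the animal. Adjusted p-values are Benjamini-Hochberg values over the 98 genes, and a gene was called at an adjusted p under 0.05. The dose trend is the slope per dose step over vehicle, 0.3, 3 and 30 µg/kg.

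Position within the liver lobule was taken from landmark genes. In each section, bins were ranked by the log2 ratio of central to portal landmark transcripts over the bin and its neighbours (9 bins), with 1 added to each sum. The 4 central landmarks on the panel were Glul, Axin2, Gulo and Cyp7a1, and the 4 portal landmarks were Cyp2f2, Hal, Sds and Gls2. The bins were divided into 5 layers. The zonation index of a gene is the log2 of its share of transcripts in the most central layer over its share in the most portal layer, with 0.5 added to each count, so positive values lie toward the central vein and negative values toward the portal tract. A landmark was left out of the ranking used for its own index. The index was tested with limma, with a mean-dependent prior, per animal. Because the index uses shares, a gene that fills central bins lowers the index of every other gene.

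Gene lists for pathways and cell types were fixed from the tissue and the treatment. Of 29 lists, 14 had at least 3 genes on the panel and were tested with limma's fry, which asks whether the genes of a list move, on balance, one way. Another 3 lists (glucose metabolism, cell cycle, endothelial markers) had too few genes to test. None of the genes of 12 lists (circadian, male-biased, iron and heme, inflammation, and markers of hepatocytes, portal endothelium, portal fibroblasts, B and plasma cells, T and NK cells, neutrophils, dendritic cells and blood) was on the panel. Lists share members: Cyp7a1, Glul, Nqo1, Axin2, Hal, Sds, Gls2, Rspo3, Wnt2 and Wnt9b each stand in more than 1. Genes named are those called with both dosed animals on the same side of both vehicle animals and with the largest changes (8 up and 8 down at 30 µg/kg, 4 and 4 at the lower doses), up to 4 members per list with the smallest p at 30 µg/kg, the 8 most central and 8 most portal genes of vehicle liver, and a fixed set of AhR targets and landmarks. Not all genes that meet this rule are reported here. Other genes named were chosen after their values were seen.

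Relations with dose step across the 8 animals were tested by exact permutation of Pearson's r and Spearman's rho, two-sided, over all pairings. The smallest p they can give with this design is 0.000794.

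Slide 4 held 8 sections of 2667562 to 5270114 transcripts, and slide 5 held 9 sections of 707286 to 1766541. Nearly all transcripts lay in tissue bins (lowest section 99.9691%). All pairs of sections within a group differed by more than sampling noise, with a lowest chi-square per degree of freedom of 85.6. Transcripts are counted once per detected spot, so intervals from counts cover counting error only. On simulated counts for the 98 genes, the abundance test at 30 µg/kg recovered 98.8% of 4-fold and 60.2% of 2-fold changes, with 2.90% of calls false. These counts had the gene proportions of vehicle liver, a common spread for all genes and as many rises as falls. The rate of false calls therefore does not cover scaling error where Cyp1a1 makes up a large share of the transcripts. The zonation test recovered 73.8% of 4-fold and 20.2% of 2-fold changes, with 4.07% of calls false. Its simulated counts were drawn within the layers already found, so errors in ranking the bins are not covered. On a simulated section the axis returned the index of 90 genes with a correlation of 0.999 and a median absolute error of 0.03. All landmarks of that section had steep, opposite gradients. It therefore cannot tell how well the axis orders bins at 30 µg/kg, where landmark transcripts were fewer.

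Alternatives tried were other scalings (total transcripts, total without Cyp1a1, number of tissue bins), limma with a trended prior in place of voom, no filter on low counts, transcripts in tissue bins only, each slide alone, values per animal and slide, the replicate number as a block, and each animal left out. For zonation they were other bin sides, tissue minimum, layer numbers and landmark choices, no smoothing, bins thinned to 20 transcripts, and transcripts per bin in place of shares. After the data were seen, an axis from vein and duct markers, shares without Cyp1a1, a stricter filter and leaving out 1 section of low axis correlation were added, as was a measure of clustering that needs no axis. For that measure, the products of a gene's counts in adjacent bins were summed over the value expected from the bins' total transcripts, on the log2 scale, for genes with at least 100 transcripts in every animal, and tested with limma.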

Results

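Spatial transcript maps of 98 genes were available for the livers of 8 male mice, 2 at each of 4 doses of TCDD (vehicle, 0.3, 3 and 30 µg/kg). Each animal gave between 3385624 and 6677242 detected transcripts over both slides. The series title names dose-dependent disruption of hepatic zonation, the ordered difference in gene use between hepatocytes near the portal tract and those near the central vein. The comparisons therefore asked which panel genes changed in amount at each dose, where their transcripts lay in vehicle liver, and how those positions changed. Cyp1a1, an AhR target that encodes a xenobiotic-metabolising enzyme, made up 0.00773% and 0.017% of the transcripts of the 2 vehicle animals. Its share was 32.6% and 24.7% at 0.3 µg/kg, 48.8% and 45.0% at 3 µg/kg, and 38.9% and 42.5% at 30 µg/kg.

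**Figure D1:**
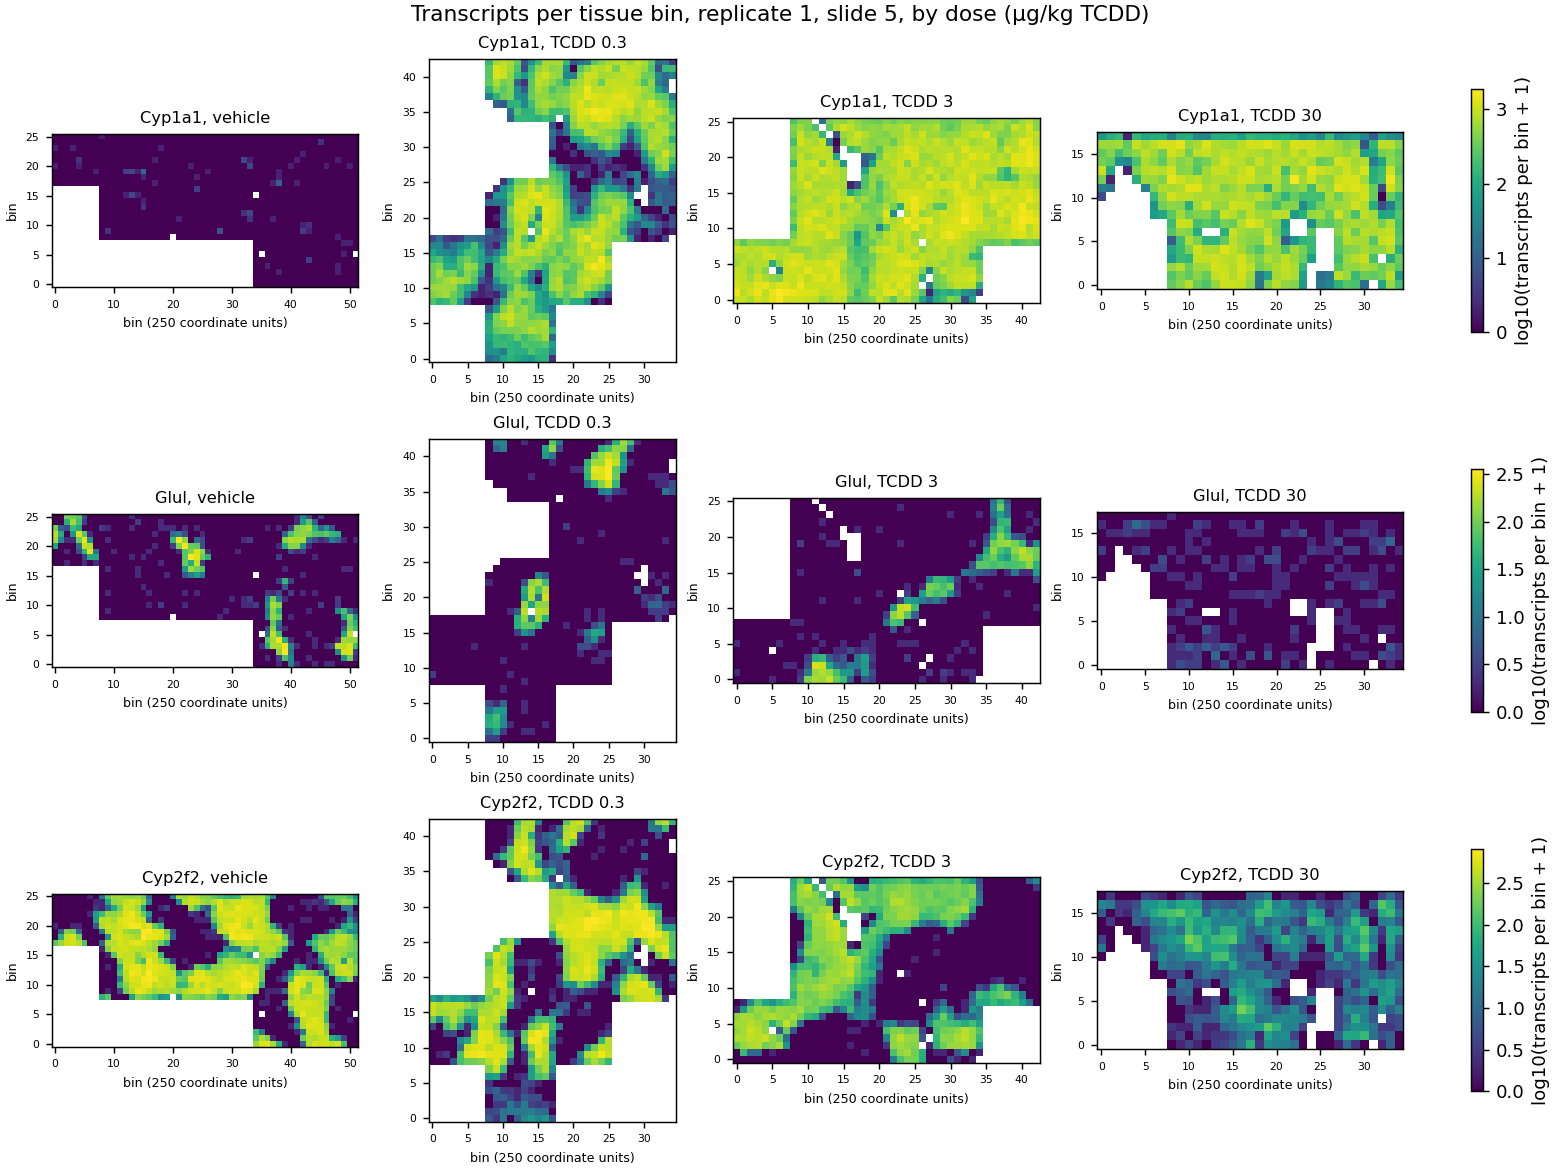
Transcripts of Cyp1a1, Glul and Cyp2f2 per tissue bin of 250 coordinate units in the slide 5 section of replicate 1 at each dose (region 1 for TCDD 30), with colour as log10(transcripts + 1) and white where no tissue was called. Glul lay in patches and Cyp2f2 in the complementary area in vehicle and at 0.3 and 3 µg/kg, and Cyp1a1 covered nearly the whole section at 3 and 30 µg/kg.

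In vehicle liver, 58 of 98 genes were zoned, 44 toward the central vein and 14 toward the portal tract (limma, n = 2 vehicle animals). The most central were Cyp7a1, the rate-limiting enzyme of bile acid synthesis (index 8.52 ± 0.57, SE), the nuclear receptor gene Esrrg (7.73 ± 0.53), Glul, which encodes glutamine synthetase (7.70 ± 0.46), and the retinol dehydrogenase gene Rdh9 (7.60 ± 0.89). Gulo, of vitamin C synthesis, followed (6.71 ± 0.67), then the aldehyde dehydrogenase gene Aldh3a2 (6.56 ± 0.41), the glutathione transferase gene Gstm3 (5.59 ± 0.47) and Csad, of taurine synthesis (5.00 ± 0.33). The most portal was the cytochrome P450 gene Cyp2f2 (−10.22 ± 0.66). Behind it stood the amino acid catabolic genes Sds (−8.05 ± 0.85), Hal (−6.02 ± 0.58) and Gls2 (−3.78 ± 0.37), and the duct cell genes Sox9 (−5.57 ± 0.45) and Krt19 (−3.36 ± 0.89). The prostaglandin synthase gene Ptges (−3.65 ± 0.86) and the growth factor gene Nrg1 (−3.59 ± 0.64) were portal as well. Among AhR targets, Nqo1 was central in vehicle (2.47 ± 0.23), whereas the indices of Tiparp (0.85 ± 0.31), Cyp1a1 (−0.70 ± 0.27) and Ahrr (−0.46 ± 0.58) did not pass. The vein endothelial Wnt pathway genes Rspo3 (4.52 ± 0.85), Wnt2 (4.47 ± 0.38) and Wnt9b (2.12 ± 0.43), which are in no landmark list, were central. The Wnt target Axin2 is 1 of the axis landmarks, but its index differed widely between the vehicle animals (3.16 ± 1.18, adjusted p = 0.0544). The calls for Krt19 ended without either vehicle animal (−3.06 and −3.67), and that for Ptges ended without vehicle replicate 2 (−2.39).

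At 30 µg/kg, 73 of 98 genes changed in abundance, 36 higher and 37 lower (limma voom, n = 2 and 2 animals). Cyp1a1 rose from 131 ± 63.7 to 318958 ± 1418 CPM (SD), a log2 change of 11.36 ± 0.43 (SE, adjusted p = 2.6e-07). Large rises were also seen in the cystine transporter gene Slc7a11 (10.07 ± 0.76), the macrophage gene Gpnmb (8.37 ± 0.73) and the AhR repressor gene Ahrr (6.70 ± 0.66). Ptges (5.09 ± 0.44), Gstm3 (4.60 ± 0.38) and the collagen gene Col1a1 (4.51 ± 0.41) were among the largest rises too. Hao1, which encodes the peroxisomal glycolate oxidase, fell furthest, from 49872 transcripts in the vehicle animals to 10 (log2 change −13.02 ± 0.50, adjusted p = 2.6e-07). The carboxylesterase gene Ces3b fell from 200651 to 164 transcripts (−11.08 ± 0.43). Hal (−6.40 ± 0.61), the growth factor receptor gene Egfr (−5.83 ± 0.50), Igfbp2 (−5.71 ± 0.36), Gls2 (−4.93 ± 0.67) and Cyp7a1 (−4.87 ± 1.01) were also among the largest falls. Egfr differed widely between the vehicle animals (194516 and 51598 transcripts), so the size of its fall is uncertain. The size of the falls of Cyp7a1 and Gls2 differed between the TCDD 30 animals (83 and 1199 transcripts, and 998 and 189), and was −2.81 and −6.00 without replicate 1 and −6.75 and −3.69 without replicate 2. Reck, a protease inhibitor gene, was detected 2 times at 30 µg/kg and 69 times in vehicle, a ratio of 0.0157 (95% exact counting interval 0.00186 to 0.0588).

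By list, 11 of the 14 tested moved one way at 30 µg/kg (fry). In the AhR battery 5 of 7 genes rose and none fell (adjusted p = 0.000373), with Cyp1a1, Ahrr, Nqo1 (3.89 ± 0.44) and Tiparp (3.50 ± 0.57) among those higher. The receptor gene Ahr (−0.39 ± 0.46) and Xdh (0.25 ± 0.26) did not pass. All 4 portal landmarks fell (adjusted p = 0.000552), with Cyp2f2 at −3.65 ± 0.27 and Sds at −3.65 ± 0.72 beside Hal and Gls2. The size of the falls of Sds and Hal also differed between the TCDD 30 animals (7582 and 1353 transcripts, and 382 and 93), and was −4.75 and −7.28 without replicate 1 and −2.36 and −5.34 without replicate 2. Of the 4 central landmarks 3 fell (adjusted p = 0.000642): Cyp7a1, Glul (−3.35 ± 0.26) and Gulo (−0.85 ± 0.27, a call kept in only 12 of 19 alternatives), while Axin2 did not pass (−0.40 ± 0.76). All 5 genes of amino acid and urea metabolism fell (adjusted p = 0.000820), among them the urea cycle gene Asl (−2.87 ± 0.37). All 3 bile acid and cholesterol genes fell (adjusted p = 0.000552), among them the sterol synthesis gene Sqle (−3.68 ± 0.28) and the bile acid receptor gene Nr1h4 (−2.01 ± 0.30). Lipid metabolism fell on balance (adjusted p = 0.000373) with 4 genes lower and 2 higher of 7. Its falls were Ces3b, the lipogenic regulator gene Srebf1 (−3.76 ± 0.34), the citrate lyase gene Acly (−3.16 ± 0.27) and the fatty acid oxidation regulator gene Ppara (−2.72 ± 0.30), and its rises the fatty acid uptake gene Cd36 (2.66 ± 0.23) and the lipoprotein receptor gene Vldlr (1.21 ± 0.27). All 3 stress response genes rose (adjusted p = 0.00392): Nqo1, the metallothionein gene Mt1 (2.99 ± 0.57) and the antioxidant regulator gene Nfe2l2 (1.48 ± 0.27).

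Markers of other cell types moved at 30 µg/kg too. All 4 genes of the extracellular matrix list rose (adjusted p = 0.000769): the actin gene Acta2 (2.15 ± 0.40) and the collagen genes Col1a1, Col1a2 (2.12 ± 0.43) and Col3a1 (1.47 ± 0.37). All 3 recruited macrophage markers rose (adjusted p = 0.000552), Gpnmb, Trem2 (3.77 ± 0.45) and Ccr2 (1.32 ± 0.39). Of the resident macrophage markers, Cd5l (1.92 ± 0.41) and Adgre1 (1.60 ± 0.46) rose, Clec4f did not pass (0.31 ± 0.31), and the list's adjusted p was 0.0461. The call of Ccr2 was lost without either vehicle animal, and that of Adgre1 without vehicle replicate 1 or TCDD 30 replicate 2. Acta2, Col3a1, Nr1h4 and Vwf lost theirs in 1 of 19 alternatives each. Of the 4 stellate cell markers Reln rose (0.99 ± 0.35, a call lost in 6 of 19 alternatives), Lrat (1.66 ± 0.69), Pdgfrb (0.66 ± 0.26) and Des (0.51 ± 0.30) did not pass, and the list's adjusted p was 0.0338. No member of the stellate, Wnt signalling or central vein endothelial list passed when adjusted over the list alone, and for lipid metabolism that adjustment gave 3 higher and 4 lower. In the other lists past the threshold at 30 µg/kg, the counts adjusted over the list alone were those over all genes. The lists that did not pass were Wnt signalling (adjusted p = 0.185), central vein endothelium (0.130; Wnt2 0.97 ± 0.36 called, but not in 7 of 19 alternatives, Wnt9b 1.10 ± 0.47 and Rspo3 −0.04 ± 0.39 not) and duct cell markers (0.115; Pkhd1 −0.65 ± 0.32, Krt19 −0.79 ± 0.60 and Sox9 −0.29 ± 0.34, none called). In the untested lists, the cell cycle genes Top2a (2.85 ± 0.36) and Ccnd1 (2.15 ± 0.39) rose, as did the glycolytic gene Pkm (2.50 ± 0.28), the gluconeogenic gene G6pc fell (−2.29 ± 0.37), and of the endothelial genes Vwf rose (1.83 ± 0.46) and Stab2 was lower (−0.59 ± 0.23), a call kept in only 7 of 19 alternatives.

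For small changes the direction depended on the scaling. The median change of the 98 genes at 30 µg/kg was 0.03 with the scaling used, 0.49 with total transcripts, 0.98 with tissue bins and 1.24 with totals without Cyp1a1. The called genes were then 43 higher and 34 lower, 49 and 29, and 52 and 25. Of the genes called lower, Gulo and Stab2 changed sign with tissue bins (0.09 and 0.35) and without Cyp1a1 (0.36 and 0.62), and Aldh3a2 (−1.07 with the scaling used) without Cyp1a1 (0.14). Genes not called, such as Rspo3 (0.91 and 1.16) and Sox9 (0.66 and 0.92), changed sign with both as well. The calls of the resident macrophage and stellate lists depended on single animals: the resident macrophage list did not pass in 7 of the 8 fits that left out 1 animal, and the stellate list in 5.

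At 3 µg/kg, 24 genes changed, 12 higher and 12 lower. Cyp1a1 (log2 change 12.00 ± 0.43), Ahrr (7.16 ± 0.66) and Tiparp (2.16 ± 0.59) were among the largest rises, and Cd36 (1.79 ± 0.23), Nqo1 (1.60 ± 0.46), Gstm3 (1.22 ± 0.35) and Nfe2l2 (1.19 ± 0.27) rose as well. Igfbp2 fell (−3.05 ± 0.35), from 78090 ± 3817 to 9598 ± 2761 CPM (SD, adjusted p = 0.000662). G6pc (−1.90 ± 0.37), Ces3b (−1.69 ± 0.29), the triglyceride regulator gene Apoa5 (−1.69 ± 0.48), Cyp2f2 (−1.44 ± 0.28) and Hao1 (−1.32 ± 0.25) fell too. Glul (−0.08 ± 0.25), Hal (−1.12 ± 0.50), Sds (−1.07 ± 0.69) and the macrophage gene Trem2 (−1.14 ± 0.55) did not pass. Of the tested lists only the AhR battery passed (adjusted p = 0.00120), with 6 of 7 genes higher over all genes and over the list alone. With totals without Cyp1a1 the median of all genes moved from −0.17 to 0.76 and the calls to 30 higher and 1 lower. With tissue bins they were 12 higher and 1 lower. Igfbp2 stayed lower under both (−2.11 without Cyp1a1, −2.60 with tissue bins), and the other falls were called only relative to the panel's median or to total transcripts. The calls of Apoa5, Cyp2f2, G6pc, Nqo1, Tiparp and Ces3b were lost in 8, 6, 5, 5, 5 and 3 of 19 alternatives. The count was 5 without vehicle replicate 1, 8 without vehicle replicate 2, 11 without TCDD 3 replicate 1 and 15 without TCDD 3 replicate 2.

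At 0.3 µg/kg Cyp1a1 rose by a log2 change of 11.35 ± 0.43 (adjusted p = 6.5e-07), from 131 ± 63.7 to 325813 ± 106023 CPM (SD), and was the 1 gene called. Cd36 (1.03 ± 0.23, adjusted p = 0.0603), Ahrr (1.78 ± 0.76), Nqo1 (1.37 ± 0.46), Tiparp (−1.08 ± 0.70) and Glul (−0.11 ± 0.25) did not pass, and 18 genes had an unadjusted p under 0.05. Cyp2f2 (−0.21 ± 0.29), Hal (−0.59 ± 0.50) and Sds (−0.99 ± 0.69) did not pass either. The AhR battery was the 1 list past the threshold (adjusted p = 0.0128, 3 of 7 higher when adjusted over the list alone), and it was lost without vehicle replicate 1 (adjusted p = 0.150), vehicle replicate 2 (0.0871), TCDD 0.3 replicate 1 (0.0620) or TCDD 3 replicate 1 (0.0506), and with the replicate number as a block (0.0675). Over all doses, 73 genes had a dose trend, 36 upward and 37 downward. The fitted slope per dose step was 3.47 ± 0.13 for Cyp1a1, although its changes from vehicle were similar at all 3 doses (11.35, 12.00 and 11.36), and 2.55 ± 0.20 for Ahrr, while the slopes of Hao1 (−4.03 ± 0.15), Ces3b (−3.42 ± 0.13) and Igfbp2 (−1.92 ± 0.11) were negative.

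Zonation at 30 µg/kg changed for 62 of 98 genes, 43 toward the portal side and 19 toward the central side (limma on the index, n = 2 and 2 animals). In all sections of this dose the central and portal landmark sums correlated positively across bins (0.120 to 0.377). In the sections of the other groups the correlation was −0.861 to −0.496. The landmarks thus did not oppose each other at 30 µg/kg, and the index there may not measure the same position as in vehicle. The 8 largest portal shifts were all in genes central in vehicle. Cyp7a1 went from 8.52 to 0.42 (change −8.11 ± 0.81), Esrrg from 7.73 to −0.32 (−8.05 ± 0.76), Rdh9 from 7.60 to 0.64 (−6.95 ± 1.25) and Glul from 7.70 to 1.30 (−6.40 ± 0.65). The xenobiotic receptor gene Nr1i3 (−6.15 ± 0.35), Gulo (−6.01 ± 0.95), Gstm3 (−5.96 ± 0.67) and Aldh3a2 (−5.78 ± 0.58) followed. Glul fell in the most central layer from 99.6 to 5.59 transcripts per bin and stood at 0.484 and 2.91 in the most portal layer. Of the 36 genes with a vehicle index above 1, 28 changed and 27 of those shifted to the portal side, some past 0 (Esrrg −0.32). The median index of the 36 went from 2.59 to 0.42. On the portal side Cyp2f2 went from −10.22 to −1.58 (8.64 ± 0.94), whereas Sds (0.21 ± 1.20) and Hal (1.83 ± 0.82) did not pass. Gls2 became more portal (−2.57 ± 0.52), a call lost in 5 of 27 alternatives and of opposite sign in thinned bins (2.37). The call of Cyp2f2 was lost on the axis from vein and duct markers. On that axis the 4 portal landmarks changed by a mean of −0.19, against 2.03 on the landmark axis, and 0 of them became more central. Clustering of Cyp2f2 over adjacent bins, which needs no axis, was similar in vehicle (0.81) and at 30 µg/kg (0.73). Of the 13 genes with an index below −1 in vehicle, 10 changed and 8 of those shifted to the central side. Their shifts include passing 0, as for Bcl11a (−1.76 and −0.93 in the vehicle animals, 2.07 and 1.76 in the TCDD 30 animals). The median index of the 13 was −3.59 in vehicle and −1.58 at 30 µg/kg.

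**Figure D2:**
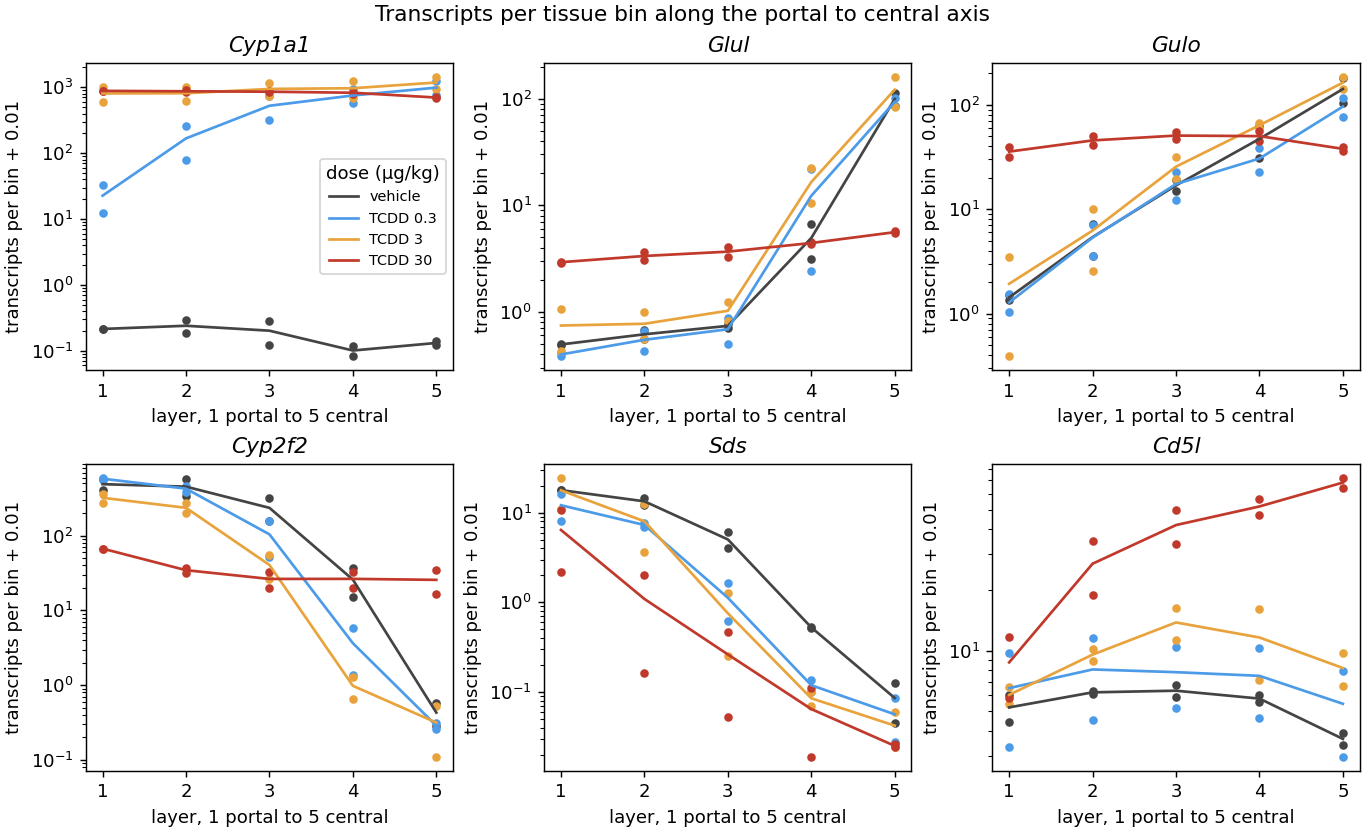
Transcripts per tissue bin of 6 genes in 5 layers from portal (1) to central (5), on a log axis with 0.01 added; points are animals and lines are means of 2 animals per dose. Cyp1a1 was graded at 0.3 µg/kg, and Glul and Gulo were far flatter across the layers at 30 µg/kg than in vehicle.

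Among the lists, all 3 bile acid and cholesterol genes (Sqle −3.27 ± 0.42, Nr1h4 −1.32 ± 0.28) and 5 of 7 lipid metabolism genes shifted to the portal side, including Pparg (−4.49 ± 0.54), Ppara (−2.50 ± 0.31), Ces3b (−2.39 ± 0.18) and Cd36 (−2.15 ± 0.29). The shift of Ces3b rested on 164 transcripts at this dose, lost its call in 3 of 27 alternatives and took the opposite sign in thinned bins (0.58). The AhR battery genes Ahr (−3.24 ± 0.51) and Nqo1 (−2.59 ± 0.33) became less central, and Cyp1a1 (0.77 ± 0.38), Ahrr (0.87 ± 0.82) and Tiparp (−0.47 ± 0.43) did not pass. All 6 macrophage markers shifted to the central side: Cd5l (3.92 ± 0.46), Trem2 (3.91 ± 0.67), Ccr2 (3.23 ± 0.60), Clec4f (2.78 ± 0.59), Gpnmb (2.72 ± 0.71) and Adgre1 (2.37 ± 0.32). With the central landmarks alone as axis none of the 6 kept its call, and on the vein and duct axis Gpnmb lost it (2.14 ± 1.07). The call of Gpnmb was kept in only 19 of 26 alternatives, and the gene had only 24 and 21 transcripts in all sections of the vehicle animals. The lymphoid regulator gene Bcl11a (3.26 ± 0.56), Ptges (3.91 ± 1.21) and Nrg1 (3.16 ± 0.91) also shifted to the central side, the calls of Ptges and Nrg1 being lost in 8 of 26 alternatives each and that of Bcl11a in 2. Wnt9b became more central (2.48 ± 0.61, kept in 21 of 26 alternatives), and Rspo3 (0.23 ± 1.20) and Wnt2 (−0.12 ± 0.54) did not pass. Among endothelial markers Vwf shifted to the portal side (−3.12 ± 0.63) and Stab2 did not pass (0.62 ± 0.33). The extracellular matrix gene Col1a2 shifted to the central side (0.93 ± 0.32, called in 12 of 27 alternatives) and Col1a1 (1.28 ± 0.55), Acta2 (2.13 ± 0.85) and Col3a1 (0.84 ± 0.43) did not pass. In the remaining lists Asl (−1.32 ± 0.29), G6pc (−1.19 ± 0.24), the stellate gene Reln (−1.35 ± 0.26), Pkm (1.01 ± 0.34) and Pdgfrb (1.11 ± 0.37) changed, the last 2 called in only 12 and 13 of 27 alternatives. No call was made for Mt1 (0.31 ± 0.77), Nfe2l2 (−0.63 ± 0.25), Xdh (−0.47 ± 0.22), Axin2 (−2.18 ± 1.67), Lrat (0.34 ± 0.53), Des (1.21 ± 0.53), Top2a (−1.10 ± 0.82), Ccnd1 (−0.12 ± 0.75) and the duct gene Pkhd1 (−0.21 ± 0.43). Krt19 (3.68 ± 1.26) and Sox9 (2.40 ± 0.64) shifted to the central side, calls kept in only 12 and 19 of 26 alternatives. They did not shift so on an axis built from vein and duct markers (−0.14 and −0.19), an alternative chosen after seeing the data. Other duct markers set the portal end of that axis, so it could hardly show a shift of duct genes. With the central landmarks alone as axis, the shifts of Gpnmb (−0.79), Wnt9b (−2.46), Col1a2 (−1.28), Krt19 (−0.19), Pdgfrb (−0.26) and Pkm (−0.08) took the opposite sign and Rspo3 changed by −4.20, and on slide 4 alone Wnt9b stood at −1.05.

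**Figure D3:**
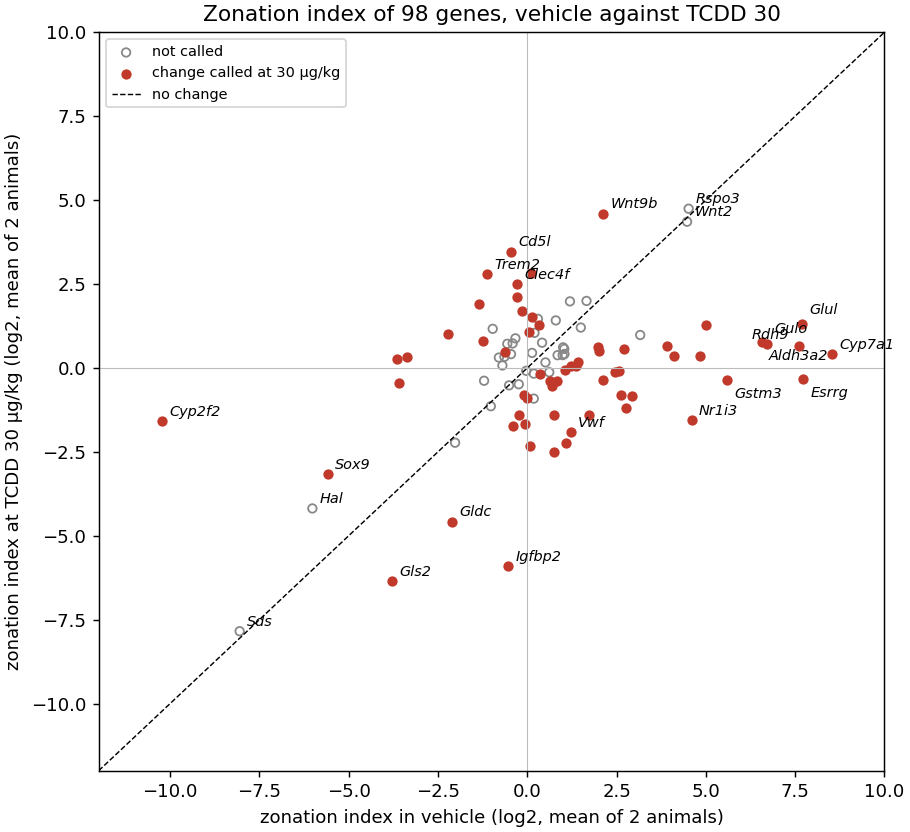
Zonation index of the 98 genes in vehicle against that at TCDD 30 µg/kg (log2, means of 2 animals each), filled where the change was called, with the dashed line marking no change. Central genes of vehicle such as Cyp7a1 (8.52 to 0.42) lie far below the line, and Rspo3, Wnt2 and Sds lie near it.

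At 3 µg/kg the index changed for 22 genes, 19 toward the portal side and 3 toward the central side. Gls2 went from −3.78 to −8.95 (change −5.17 ± 0.52), Igfbp2 from −0.53 to −5.58 (−5.05 ± 0.48), Hao1 to −2.41 (−3.91 ± 0.49) and Cyp7a1 from 8.52 to 5.28 (−3.25 ± 0.81, kept in 16 of 27 alternatives). Ahrr (3.65 ± 0.82), Nrg1 (3.28 ± 0.91) and Tiparp (1.86 ± 0.43) became more central, calls kept in only 14 of 26, 7 of 26 and 11 of 27 alternatives. Glul (−0.65 ± 0.65), Cyp2f2 (−0.65 ± 0.94), Sds (−1.52 ± 1.20), Hal (−1.75 ± 0.82), Nqo1 (−0.31 ± 0.33) and Cyp1a1 (0.89 ± 0.38) did not pass. Counted as transcripts per bin in place of shares, 8 genes were called, 3 more central and 5 more portal. Single animals weighed heavily at this dose: the count was 8 and 7 without vehicle replicate 1 and 2, 6 without either TCDD 0.3 animal and 12 without TCDD 3 replicate 2.

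At 0.3 µg/kg Cyp1a1 became strongly central, from an index of −0.70 in vehicle to 5.13 (change 5.83 ± 0.38, adjusted p = 0.000262), against 0.19 at 3 µg/kg and 0.07 at 30 µg/kg. Its transcripts per bin ran from 22.6 in the most portal layer to 988 in the most central, compared with 806 and 1182 at 3 µg/kg and 883 and 699 at 30 µg/kg. Ahrr (4.57 ± 0.82) and Nrg1 (4.84 ± 0.91) also became more central, calls kept in only 18 and 20 of 26 alternatives. Ahrr had only 3 transcripts over the most central and most portal layers in a vehicle animal. Nrg1 took the opposite sign on slide 5 alone (−0.33, and −0.26 at 3 µg/kg). Of the 18 genes called, 15 shifted to the portal side, led by Reck (−3.61 ± 0.72, few transcripts), Cyp7a1 (−3.42 ± 0.81), Igfbp2 (−2.77 ± 0.48) and Bhmt, of methionine synthesis (−2.43 ± 0.52). Glul (−0.26 ± 0.65), Nqo1 (0.79 ± 0.33), Tiparp (−1.04 ± 0.43), Cyp2f2 (−1.29 ± 0.94), Sds (−0.65 ± 1.20) and Hal (−1.60 ± 0.82) did not pass. None of the 15 portal shifts remained a call as transcripts per bin (3 genes more central, 0 more portal) or with Cyp1a1 left out of the shares (8 more central, 0 more portal). The largest of them shrank only in part: per bin Igfbp2 stood at −2.25 ± 0.50 (adjusted p = 0.0657) and Cyp7a1 at −2.92 ± 0.79 (adjusted p = 0.0729). The count was 5 and 4 without vehicle replicate 1 and 2, and 6 and 1 without TCDD 0.3 replicate 1 and 2.

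Across doses, 60 genes had a zonation trend, 42 toward the portal side and 18 toward the central side. Among the steepest were Esrrg (slope −2.50 ± 0.24 per dose step), Cyp7a1 (−2.42 ± 0.26), Nr1i3 (−1.98 ± 0.11), Glul (−1.96 ± 0.21), Igfbp2 (−1.84 ± 0.15) and Cyp2f2 (2.66 ± 0.30). A slope need not mean a graded change. For Glul and Cyp2f2 no change passed at 0.3 or 3 µg/kg, where the estimates for Cyp2f2 had the opposite sign, so their slopes rest on 30 µg/kg. The mean index of the 4 central landmarks was 6.52 ± 1.39 in vehicle, 4.94 ± 0.05 at 0.3 µg/kg, 5.73 ± 1.56 at 3 µg/kg and 0.85 ± 0.45 at 30 µg/kg (SD, n = 2 animals each). For the 4 portal landmarks it was −7.02 ± 0.76, −8.48 ± 0.01, −9.29 ± 1.27 and −4.99 ± 0.91. The central landmark mean was related to dose step with r = −0.785 (exact permutation p = 0.0198, rho = −0.781, permutation p = 0.0349, n = 8), and the portal mean with r = 0.337 (exact permutation p = 0.409, rho = 0.293, permutation p = 0.513, n = 8). The correlation of central with portal landmarks across bins, a measure of how sharp the axis is, averaged −0.782 in vehicle, −0.721 at 0.3, −0.813 at 3 and 0.274 at 30 µg/kg, with r = 0.750 against dose step (exact permutation p = 0.0429, rho = 0.488, permutation p = 0.247, n = 8). Transcripts per tissue bin gave r = 0.633 (exact permutation p = 0.0849, rho = 0.683, permutation p = 0.0825, n = 8). In this family of 4 relations the adjusted values of r were 0.0794, 0.409, 0.0857 and 0.113, so none passed. The TCDD 30 animals stood apart: among the 6 animals below that dose, r was −0.304, −0.829, −0.191 and 0.572 (exact permutation p = 0.556, 0.0667, 0.822 and 0.267). With any 2 of the 4 vehicle and TCDD 30 animals left out (6 choices), r ranged from −0.757 to −0.304, −0.829 to 0.722, −0.191 to 0.817 and 0.297 to 0.813, so the relations of the first 3 measures rest on the TCDD 30 animals.

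The slides gave similar estimates for the same animals. Across 96 genes, which are not independent replicates, the 30 µg/kg abundance changes of slide 4 and slide 5 correlated with r = 0.978, and 72 of 72 called genes had the same sign. For zonation r was 0.929 and 61 of 62 genes had the same sign, Wnt9b being the exception. At 3 µg/kg the zonation correlation was 0.629 and at 0.3 µg/kg it was 0.645, with Nrg1 of opposite sign at both and Acod1 at 3 µg/kg.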

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

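The alternatives were chosen before the data were examined, except the vein and duct axis, the shares without Cyp1a1, the filter of 10 transcripts in every animal and leaving out the section of low axis correlation (TCDD 0.3 replicate 2, slide 4), which were chosen only after the results had been seen. With all animals kept, abundance calls ranged from 66 to 79 at 30 µg/kg, 9 to 31 at 3 and 1 to 9 at 0.3, and zonation calls from 36 to 65, 5 to 27 and 3 to 28. Of the 45 named genes called for abundance at 30 µg/kg, 35 kept their call and direction in all settings, and of 38 for zonation, 15 did. The filter on low counts removed no gene. The thinned bins left 76 genes to test and cost depth in all groups, and slides used alone held fewer transcripts. For the other differences given here the cause was not tested.

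Abundance calls at 0.3 µg/kg were 7 with totals without Cyp1a1, 2 with limma's trended prior, 9 with values per animal and slide and 3 with the replicate block. At 3 µg/kg they were 13 with tissue bins, 9 on slide 5 and 9 without the section of low axis correlation. Lists past the threshold at 3 µg/kg were 4 without Cyp1a1, 2 on slide 5 and 4 with values per animal and slide, and at 0.3 µg/kg 0 with the replicate block. Scaled without Cyp1a1, genes called under either scaling that changed sign included Gulo (0.36), Rspo3 (1.16), Sox9 (0.92), Stab2 (0.62) and Aldh3a2 (0.14) at 30 µg/kg and Glul at 3 µg/kg (0.86). Ahr (0.81), Axin2 (0.82), Krt19 (0.42) and Pkhd1 (0.56) turned without a call. The duct cell list at 30 (adjusted p = 0.0435) and lipid metabolism at 3 µg/kg (adjusted p = 0.0369) also changed direction, by construction of the larger factor. Of the genes called, tissue bins turned Gulo (0.0929) and Stab2 (0.35).

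Zonation calls at 3 µg/kg were 8 per bin, 9 with central landmarks alone, 7 on slide 4, 6 on slide 5, 5 in thinned bins and 8 without the section of low axis correlation. At 0.3 µg/kg they were 3 per bin, 8 on slide 5, 3 in thinned bins, 28 with values per animal and slide and 8 in shares without Cyp1a1. Thinned bins gave 35 in vehicle, 36 at 30 µg/kg and 31 for the trend, and turned Ces3b (0.58), Col1a2 (−0.65) and Gls2 (2.37) at 30 and Gls2 (0.22) at 3 µg/kg. Central landmarks alone turned Col1a2 (−1.28), Gpnmb (−0.79), Krt19 (−0.19), Pdgfrb (−0.26), Pkm (−0.0759), Rspo3 (−4.20) and Wnt9b (−2.46) at 30 µg/kg. Wnt9b also turned on slide 4 (−1.05), Nrg1 on slide 5 (−0.26 at 3 and −0.33 at 0.3 µg/kg), and Krt19 (−0.14) and Sox9 (−0.19) on the vein and duct axis, where the portal landmark trend was r = −0.248. Transcripts per bin against dose step gave r = 0.750 on slide 5, with an unadjusted p now under 0.05, and the sharpness of the axis gave r = 0.755 without the section of low axis correlation, with an unadjusted p no longer under 0.05.

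With 1 animal left out, the lone animal of its group was assumed to vary like the other groups. Abundance calls then ranged from 62 to 77 at 30 µg/kg and for the trend, from 5 (without vehicle replicate 1) to 22 at 3 and from 1 to 1 at 0.3 µg/kg. Lists ranged from 9 to 13, 1 to 2 and 0 to 2, with 0 at 0.3 µg/kg without either vehicle animal, TCDD 0.3 replicate 1 or TCDD 3 replicate 1, and 2 without either TCDD 30 animal. Zonation calls ranged from 36 (without vehicle replicate 2) to 62 in vehicle, 48 to 65 at 30, 6 to 21 at 3, 1 (without TCDD 0.3 replicate 2) to 24 at 0.3 µg/kg and 44 to 62 for the trend. For the relations with dose, of which none passed when adjusted, r ranged from −0.931 to −0.695 for central landmarks, whose unadjusted p was no longer under 0.05 without vehicle replicate 1 (−0.714) or either TCDD 30 animal (−0.703 and −0.695), and from −0.00373 (without TCDD 30 replicate 2) to 0.553 for portal landmarks. It ranged from 0.643 to 0.844 for the sharpness of the axis, whose unadjusted p rose over 0.05 without any 1 of the vehicle, TCDD 0.3 or TCDD 30 animals, and from 0.439 to 0.779 (unadjusted p under 0.05 without vehicle replicate 1) for transcripts per bin.

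Animals with the same replicate number deviated together with correlations of −0.0488 to 0.274 over the 6 pairs of groups, so the numbers were not taken as pairs. With the replicate block, abundance calls were 74, 27 and 3 at 30, 3 and 0.3 µg/kg, zonation calls 56, 17 and 15, and lists 10, 1 and 0. The zonation changes of Col1a2 (adjusted p = 0.0598), Pdgfrb (0.0506) and Pkm (0.0581) at 30 µg/kg lost their calls with it.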

Other observations

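All tests in this part were chosen only after the results they bear on had been seen. Clustering of a gene's transcripts over adjacent bins, which needs no axis, changed for 32 of 78 genes at 30 µg/kg, 15 more clustered and 17 less (limma, n = 2 and 2 animals). The genes that became more clustered fell in abundance in 12 of 15 cases, where 37 of all 98 panel genes fell. Hao1, Ces3b, Hal and Cyp7a1, among the largest falls, had too few transcripts for this measure. Of the 9 genes portal in vehicle that had a value, 3 became more clustered (Gls2, Sds and Gldc) and 1 less. Gls2, of glutamine breakdown, went from 0.48 to 2.61 (log2 change 2.13 ± 0.31, SE, adjusted p = 0.000598), the serine dehydratase gene Sds rose by 1.89 ± 0.38, the sterol gene Sqle by 1.63 ± 0.20, Igfbp2 by 1.54 ± 0.21 and the glycine cleavage gene Gldc by 1.13 ± 0.25. The hepatocyte regulator gene Prox1 (0.85 ± 0.15), Asl (0.68 ± 0.11), Egfr (0.67 ± 0.10) and the resident macrophage gene Cd5l (0.46 ± 0.14) became more clustered as well.

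Genes that became less clustered included the central genes Glul (−2.75 ± 0.52), Rdh9 (−1.64 ± 0.33), Gstm3 (−1.55 ± 0.27), Vldlr (−1.54 ± 0.28), Gulo (−1.27 ± 0.25), Aldh3a2 (−1.10 ± 0.20) and Cd36 (−1.08 ± 0.18), with the Wnt target Axin2 (−1.32 ± 0.26) and the collagen gene Col1a1 (−2.33 ± 0.74). Gstm3, Vldlr, Cd36 and Col1a1 became less clustered while they rose in abundance. Cyp1a1 had a lower clustering value at all 3 doses (−3.06, −3.69 and −3.71). Its vehicle value differed between the animals (3.73 ± 2.02, SD) and rested on 980 transcripts. In dosed animals Cyp1a1 itself made up 24.7 to 48.8% of the totals it is set against, which pulls its value toward 0. The lower value is therefore no sign of a lost spatial pattern, and at 0.3 µg/kg Cyp1a1 was strongly graded along the axis. Wnt2, the vein endothelial gene, kept a similar value (1.06 in vehicle, 1.17 at 30 µg/kg, change 0.11 ± 0.22).

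At 0.3 µg/kg 15 of the 18 zonation calls pointed to the portal side. The median index of the 97 genes other than Cyp1a1, taken per animal, changed by −0.59 ± 0.15 in shares (SE, n = 2 and 2 animals). A loss of detection where Cyp1a1 is dense would also lower the index counted per bin, but the median of that index changed by −0.0858 ± 0.176. With Cyp1a1 left out of the shares the median changed by 0.302 ± 0.165. Leaving it out adds the same amount to the index of nearly every other gene of an animal. This value therefore cannot tell whether Cyp1a1 filling the central share was the cause. That Cyp1a1 in central bins lowers the share index of the other genes follows from how the index is built. Counted per bin, their median did not fall beyond its spread. Whether Cyp1a1 made up the whole portal shift stays open, as does whether single genes such as Cyp7a1 (−2.52 without Cyp1a1, −3.42 with it) moved at this dose.

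At 30 µg/kg the 36 genes central in vehicle lost most of their zonation. Their median index, taken per animal, changed by −2.10 ± 0.10 (SE of the difference between 2 and 2 animals). If the landmark axis had merely stopped ordering the bins, an axis from vein and duct markers that still ordered them would show zonation kept. On that axis the animals' median index changed by −1.96 ± 0.16. How well it orders bins at 30 µg/kg was not measured by itself, which limits the test. Rspo3, Wnt2 and Wnt9b, each left out of its own ranking, kept an index of at least 1 in size on it. So did Cyp2f2, Sds, Hal and Gls2. The median number of transcripts per bin was higher at 30 µg/kg by 0.548 ± 0.396 (log2). That total includes Cyp1a1, which made up 38.9% and 42.5% of the transcripts of the TCDD 30 animals. It therefore cannot tell whether lower depth for the other genes blurred the layers. The vein and duct axis took the place of clustering as the test after both values were seen: the median clustering of 31 of these genes went from 0.677 to 0.207, but the median of their own changes was −0.236, with 12 lower and 1 higher. Whether the hepatocytes lost the programme or the lobule structure changed stays open, since vein genes kept their index on the landmark axis (mean 4.56, 3.70 in vehicle) but not with central landmarks alone (Rspo3 −4.20, Wnt2 −3.60 and Wnt9b −2.46), Wnt9b turned on slide 4 (−1.05) and the endothelial gene Vwf shifted to the portal side (−3.12 ± 0.63).

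All 6 macrophage markers shifted to the central side at 30 µg/kg (mean change 3.16 ± 0.26), though the vehicle index of Gpnmb rests on few transcripts. If bins poor in portal landmarks had been ranked as central, the shift would be large with the portal landmarks alone as axis and small with the central ones alone, as it was (3.39 ± 0.17 and 0.566 ± 0.335, though Rspo3, a vein gene, itself changed by −4.20 on the latter). As the whole cause this is argued against by the vein and duct axis, as far as that axis orders bins at 30 µg/kg. It uses neither set and gave 2.78 ± 0.18, but a part of the shift may come from such ranking. A lower hepatocyte share in central bins would shift endothelial and stellate markers alike, but the macrophage markers moved by 2.81 ± 0.34 more than these 6 on that axis and by 3.36 ± 0.52 more on the landmark axis (3.02 ± 0.21 and 2.64 ± 0.77 in a first form that counted the 3 duct markers, which are part of the vein and duct axis). More macrophages toward the central vein at this dose stays a candidate explanation, and other cell states that express these genes were not examined.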
